A study of Homo sapiens with 18 samples.

How the data were processed

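Total RNA pools of H9 human embryonic stem cells and of cells derived from them were measured on 1-colour Affymetrix arrays with 54675 probe sets. The groups and pool numbers were taken from the sample titles and descriptions. The deposited table holds 1 linear signal (intensity) per probe set and array. That its values had been scaled is taken from the values themselves: the 2% trimmed mean was 150.016 to 150.026 on all 18 arrays. The summarisation software, the background method, detection calls and the authors' own tests are not given in the sources used here. Because the trimmed means agreed, no further normalization was applied in the main tests. The median signals did not agree, at 48.7 to 50.8 on 4 arrays and 25.2 to 32.7 on the other 14. The rule set beforehand also named differing medians as a ground for quantile scaling, which was run only as an alternative. Without detection calls a low signal has no bound here, and the number of arrays limits the precision.

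Signals were analysed as log2(signal + 16), a scale that understates the changes of low genes. Probe sets were named from the platform annotation: 41097 named 1 gene, 1801 named several, and 11777 were unnamed here, 56 of these being control probe sets of a total of 62. Of a gene's probe sets those ending in _x_at were left out where another existed, and of the rest the probe set with the highest mean was kept, which gave 19775 genes; 19738 of their symbols are in the current gene table, and the update changed 0 symbols. POU5F1, among others, had no probe set that named it alone and is not analysed here. Ratios of the 3' to the 5' control probe sets of ACTB and GAPDH were used as a check of RNA quality; for GAPDH they were 0.876 to 1.24 on the 18 arrays, the highest signals were 15234 to 31700 and the 95th percentiles 909 to 1103. The first 3 principal components held 34.8%, 19.7% and 7.85% of the variance.

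Groups were compared with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 18 arrays, which leaves 12 residual degrees of freedom, then eBayes, with Benjamini-Hochberg adjusted p under 0.05 over the 19775 genes. The 6 comparisons were day 6 against ES cells, untreated day 10 against day 6, untreated day 17 against untreated day 10, bFGF against none at day 10 and at day 17, and the difference of the last 2. For 27 gene lists, camera (limma) with its preset correlation between genes was run two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The lists were pluripotency, Nodal and activin, early neuroectoderm, forebrain and eye field, midbrain and hindbrain, posterior HOX and CDX, ventral and dorsal neural tube, neurons, glia, neural crest, mesendoderm, mesenchyme and muscle, endoderm, trophoblast, surface ectoderm, FGF and ERK targets, BMP targets, Wnt targets, Notch, retinoic acid, cholesterol synthesis, hypoxia and glycolysis, p53 targets, cell cycle, extracellular matrix, and ribosomal proteins as a control. Lists share members: 8 of the 16 measured BMP targets, and 4 members each of the dorsal neural tube, neural crest and trophoblast lists, are also in another list.

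Genes were named by a fixed rule: in each comparison, among genes past the test whose groups of 3 did not overlap, the 12 with the largest increase and the 12 with the largest decrease that carry an approved symbol, and of each list up to 4 members with the largest absolute change; for the difference of the bFGF effects it took 6 each way, without the condition on overlap. Groups, tests, lists, this rule and most alternatives were chosen before the data were examined. Alternatives chosen after seeing the data were the fits without the 4 arrays with raised low signals, with that array set as a term and without pool 2, and the list tests without these arrays, after quantile scaling and without each array in turn, and for 2 lists also without each pool. Lists of liver and yolk sac, choroid plexus, and retina and lens genes were also added then. The other alternatives were pseudocounts of 1 and 64, quantile scaling, the upper 60% of genes by mean signal, a trended and robust variance prior, a fit of the compared groups alone, the mean of a gene's probe sets, all probe sets, the pool number as a fixed or random block, fry, and leaving out each array.

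The titles number the pools 1 to 3 in each group, except that the number of ES pool 1 follows the order of the samples. The labels give cell passages for the ES and day 6 pools: 27, 28 and 31 for ES pool 1 and for day 6 pools 1 and 2, 24, 25 and 26 for ES pool 2, and 26, 28 and 29 for pool 3 of both. For the neuroepithelial groups they give none, so that where nothing says that pools came from separate cultures, p-values measure only the spread between these samples. One bFGF day 10 pool is numbered 2 in its title and 1 in its description, and the title was used. Whether equal numbers pair the arrays was checked by the correlation, across genes, of deviations from the group means. This lay at 0.209 to 0.383 for day 6 and ES cells, 0.365 to 0.621 for day 17 and day 10, 0.394 to 0.668 for bFGF at day 10, 0.317 to 0.653 for bFGF at day 17, and 0.317 to 0.693 over the 18 pairs of the difference. Each was over 0.1, and these comparisons were taken as paired. The main fit has no pool term, so its counts and p-values do not use this pairing, and the block was run as an alternative. The check cannot tell pairing from a signal shared by all pool 2 arrays, which would raise each of these values. ES pool 2 and day 6 pool 2 list different passages.

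In simulated data 200 of 19775 genes were changed, 100 at a log2 change of 1 and 100 at 2. Recovered were 24% and 83% for day 6 against ES cells (5 false calls), 24% and 75% for day 10 against day 6 (7), 27% and 80% for day 17 against day 10 (3), 25% and 77% for bFGF at day 10 (5), 22% and 79% for bFGF at day 17 (2), and 7% and 45% for the difference (4). In each comparison camera found the raised list and not the unchanged one (lowest p 0.211). These rates need not hold in the data, where a control list was called. Figures used matplotlib 3.10.9 in Python 3.11.15.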

Results

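H9 is a human embryonic stem (ES) cell line. Its cells were profiled on Affymetrix expression arrays before and during differentiation to neuroepithelium, the epithelial precursor of the brain and spinal cord. 18 arrays covered 6 groups of 3 RNA pools: ES cells, embryoid bodies at day 6, neuroepithelium at day 10 and at day 17 without added growth factor, and neuroepithelium at day 10 and day 17 grown with basic fibroblast growth factor (bFGF, also called FGF2) from day 6. Embryoid bodies are aggregates grown in suspension, and by day 17 neuroepithelial cells in such cultures form rosettes. The labels give 20 ug/ml bFGF for the day 10 pools and 20 ng/ml for the day 17 pools, and which unit applied at day 10 was not resolved.

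All 18 arrays had been scaled to 1 level. Pool 2 of the 4 neuroepithelial groups had raised low signals: the median signal of these 4 arrays was 48.7 to 50.8, against 25.2 to 32.7 on the other 14, and their 5th percentile was 3.30 to 3.46 against 1.23 to 1.73. Pool 2 of all 6 groups had higher ACTB 3' to 5' ratios (2.27 to 2.64, other arrays 1.17 to 1.75), a measure of RNA integrity. Yet its GAPDH ratio was the lowest in each group. Each of the comparisons among the neuroepithelial groups has 1 of the 4 arrays in each group, and day 10 against day 6 has 1 at day 10 and 0 at day 6. Signals are given as mean ± SD (n = 3), and log2 changes, on the log2(signal + 16) scale, as estimate ± standard error. Across genes, arrays of 1 group correlated at 0.921 to 0.978 (median 0.957, 18 pairs) and arrays of different groups at 0.859 to 0.979 (median 0.934, 135 pairs).

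**Figure D1:**
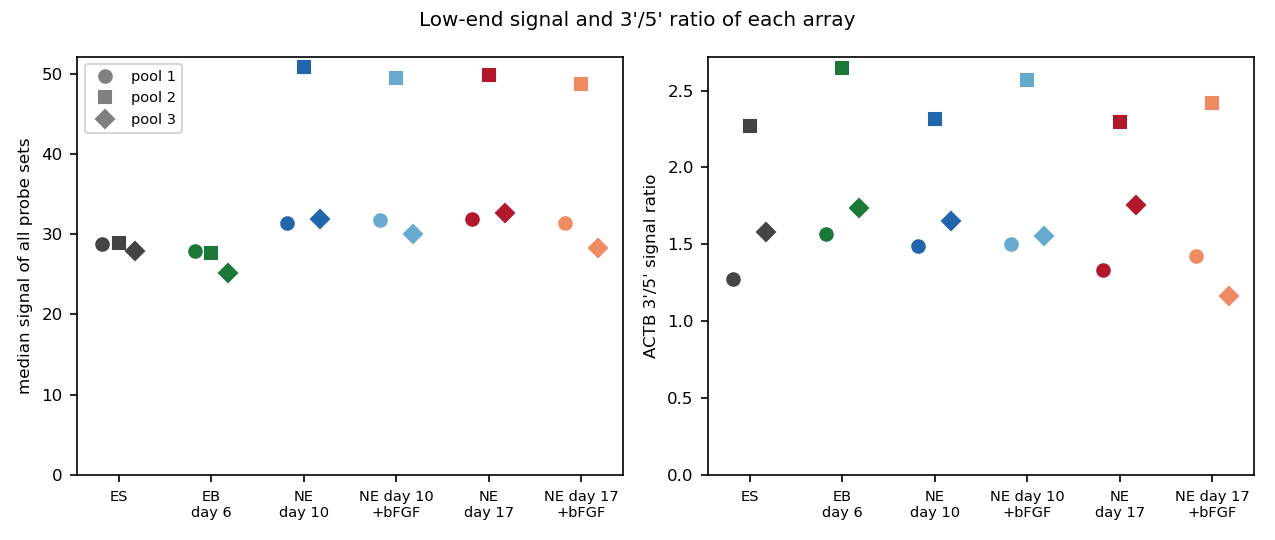
Array quality by group. Each point is 1 array, with its median signal and its ACTB 3' to 5' ratio on the vertical axes, and pool 2 of the 4 neuroepithelial groups lies at median signals of 48.7 to 50.8 against 25.2 to 32.7 on the other arrays.

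The first comparison asked what changed between ES cells and day 6 embryoid bodies. NANOG, a core pluripotency factor, fell to 291 ± 69.2 against 3203 ± 382 (log2 change -3.41 ± 0.31), and LEFTY1, a secreted inhibitor of Nodal, to 49.7 ± 17.6 against 1326 ± 455 (-4.32 ± 0.40). LHX2 and SIX3, transcription factors of the forebrain and eye field, rose to 979 ± 415 against 7.24 ± 9.05 (5.40 ± 0.29) and 2136 ± 121 against 58.1 ± 53.1 (5.08 ± 0.32). PAX6, a transcription factor of the neural plate and eye, rose to 725 against 46.6 (3.59 ± 0.26), and TFAP2A, a regulator of neural crest and surface ectoderm, to 670.3 against 34.96 (3.82 ± 0.40). In total 762 of 19775 genes differed, 434 higher and 328 lower in embryoid bodies, of which 590 changed at least 2-fold.

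Other large increases were in DLK1, a membrane protein related to Notch ligands (4.98), PRTG, an immunoglobulin superfamily receptor (4.56), HAPLN1, which links hyaluronan to proteoglycans (4.50), EPAS1, a hypoxia-inducible factor subunit (4.48), and ALDH1A2, which makes retinoic acid (4.12). GREB1L (4.29) and FLRT3 (4.06) also rose. CAV1, the coat protein of caveolae (-3.43), COL1A1, a fibrillar collagen chain (-3.03), CXCL5, a chemokine (-3.08), APELA, a peptide ligand of the apelin receptor (-2.93), and S100A6, a calcium-binding protein (-2.91), fell. The largest adjusted p among these was 0.00157, and each of the 24 largest changes kept its call when any 1 array was left out.

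Of the gene lists, pluripotency fell (median log2 change -0.73, adjusted p = 1.91e-09, and adjusted p = 0.000695 with an estimated correlation): 7 of 19 measured members fell over all genes and 7 adjusted over the list alone, among them GAL (-2.34), CD9 (-2.09) and DPPA2 (-1.91). Early neuroectoderm rose (median log2 change 1.20, adjusted p = 5.06e-25, and adjusted p = 0.000122 with an estimated correlation). Among 20 measured members, 9 rose over all genes and 16 adjusted over the list alone, including MEIS2 (2.94) and DACH1 (2.77). Forebrain and eye field rose as well (median log2 change 1.36, adjusted p = 2.54e-13, and adjusted p = 0.000695 with an estimated correlation). By member, 7 of 15 rose over all genes and 9 adjusted over the list alone; HESX1 reached 2777 against 480.2 and LHX5 114 against 6.01. Midbrain and hindbrain rose by less (median log2 change 0.19, adjusted p = 0.000310, and adjusted p = 0.0154 with an estimated correlation), through IRX1 (2.53) and PAX2 (2.29), and 4 of 17 measured members rose over all genes and 6 adjusted over the list alone. Dorsal neural tube rose (median log2 change 0.49, adjusted p = 5.41e-07, and adjusted p = 0.0154 with an estimated correlation), with MSX2 at 1.77 and GLI3 at 1.64, and 4 of 13 measured members rose over all genes and 5 adjusted over the list alone.

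BMP targets (median log2 change 0.89, adjusted p = 9.58e-08, and adjusted p = 0.00599 with an estimated correlation) and Wnt targets (median log2 change 0.51, adjusted p = 3.57e-08, and adjusted p = 0.00599 with an estimated correlation) rose. For BMP, 7 of 16 measured members rose and 0 fell over all genes, against 10 and 2 adjusted over the list alone, including GATA3 (2.94) and ID2 (1.44), and 8 of its 16 members are also in another list. For Wnt, 6 of 15 measured members rose over all genes and 7 adjusted over the list alone, including SP8 (2.99) and LEF1 (2.27), which are also regulators of forebrain patterning and of Wnt transcription. The trophoblast list rose (median log2 change 0.29, adjusted p = 0.000546, and adjusted p = 0.0169 with an estimated correlation). Singly, 4 of the 13 rose over all genes and 5 adjusted over the list alone; its largest changes were in EPAS1, GATA3, HAND1 (2.31) and VGLL1 (1.96), while the trophoblast factor CDX2 was at 2.63 against 13.4 (-0.62). Mesenchyme and muscle fell (median log2 change -0.67, adjusted p = 0.000163, and adjusted p = 0.0154 with an estimated correlation), although LUM, a matrix proteoglycan, rose (3.41), and 1 of 16 measured members rose and 4 fell over all genes, against 1 and 5 adjusted over the list alone. Hypoxia and glycolysis fell (median log2 change -0.58, adjusted p = 5.20e-08, and adjusted p = 0.0154 with an estimated correlation), with ADM at -2.27 and P4HA1 at -1.15, and 5 of 18 measured members fell over all genes and 6 adjusted over the list alone.

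Another 7 lists were called at the preset correlation alone. Nodal and activin genes fell as a list, with a median log2 change of -0.82 (adjusted p = 0.00253, and adjusted p = 0.1004 with an estimated correlation). Here 1 of 7 measured members rose and 1 fell over all genes, against 1 and 3 adjusted over the list alone, LEFTY1 and, upward, FST (1.53), an activin antagonist. Among the 11 measured neural crest genes, 6 rose and 2 fell over all genes, against 7 and 3 adjusted over the list alone, with TFAP2B at 3.32 and SNAI2 at 2.25. Their median was 1.48, and the list rose with adjusted p = 0.000310, and adjusted p = 0.105 with an estimated correlation. Endoderm genes rose as a list, with a median log2 change of 0.32 (adjusted p = 0.0457, and adjusted p = 0.236 with an estimated correlation). Of its 13 measured members, 0 rose over all genes and 1 adjusted over the list alone, with GATA6 at 0.78. Endoderm lost the call without ES pool 1 (adjusted p 0.0651), ES pool 2 (0.0633), ES pool 3 (0.0698), day 6 pool 2 (0.0699) or day 6 pool 3 (0.0863) or with the pool number as a block (0.0568). Notch pathway genes rose as a list, with a median log2 change of 0.35 (adjusted p = 0.0238, and adjusted p = 0.167 with an estimated correlation). Among 15 measured members, 2 rose and 1 fell over all genes, against 2 and 1 adjusted over the list alone. Notch lost the call without ES pool 1 (adjusted p 0.0626), ES pool 3 (0.0522) or day 6 pool 1 (0.0744). Cholesterol synthesis genes rose as a list, with a median log2 change of 0.35 (adjusted p = 0.00369, and adjusted p = 0.0849 with an estimated correlation). By member, 1 of 15 rose over all genes and 1 adjusted over the list alone. Among the 13 measured p53 targets, 0 rose and 1 fell over all genes, against 2 and 1 adjusted over the list alone. Their median was -0.45, and the list fell with adjusted p = 0.0216, and adjusted p = 0.109 with an estimated correlation. Extracellular matrix genes rose as a list, with a median log2 change of 0.47 (adjusted p = 0.000310, and adjusted p = 0.166 with an estimated correlation). Singly, 4 of the 18 rose and 1 fell over all genes, against 7 and 1 adjusted over the list alone, including HAPLN1 and SPON1 (2.77).

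The remaining 10 lists were not called (adjusted p 0.0516 to 0.679). Surface ectoderm came nearest (median 0.09, adjusted p = 0.0516, and 0.0367 with the pool number as a block). Posterior HOX and CDX genes had a median of -0.00, mesendoderm 0.27, cell cycle 0.13 and the ribosomal control list 0.06. For neurons the median was -0.01, against a mean of 0.30 and an upward test, and for FGF and ERK targets the median was 0.09, against a mean of -0.12 and a downward test. The pools of the compared groups lay apart for 761 of the 762 genes, and for 19.8% of all genes, where chance gives 10%. The count was 1454 (832 higher, 622 lower) with the pool number as a block, 468 without day 6 pool 1 and 462 without day 6 pool 3. When a gene's probe sets were averaged PAX2 (1.21), VGLL1 (0.46), P4HA1 (-0.70) and LUM (1.83) lost their calls, LUM also with a pseudocount of 64 (2.03) and P4HA1 also without pool 2 (-1.15).

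**Figure D2:**
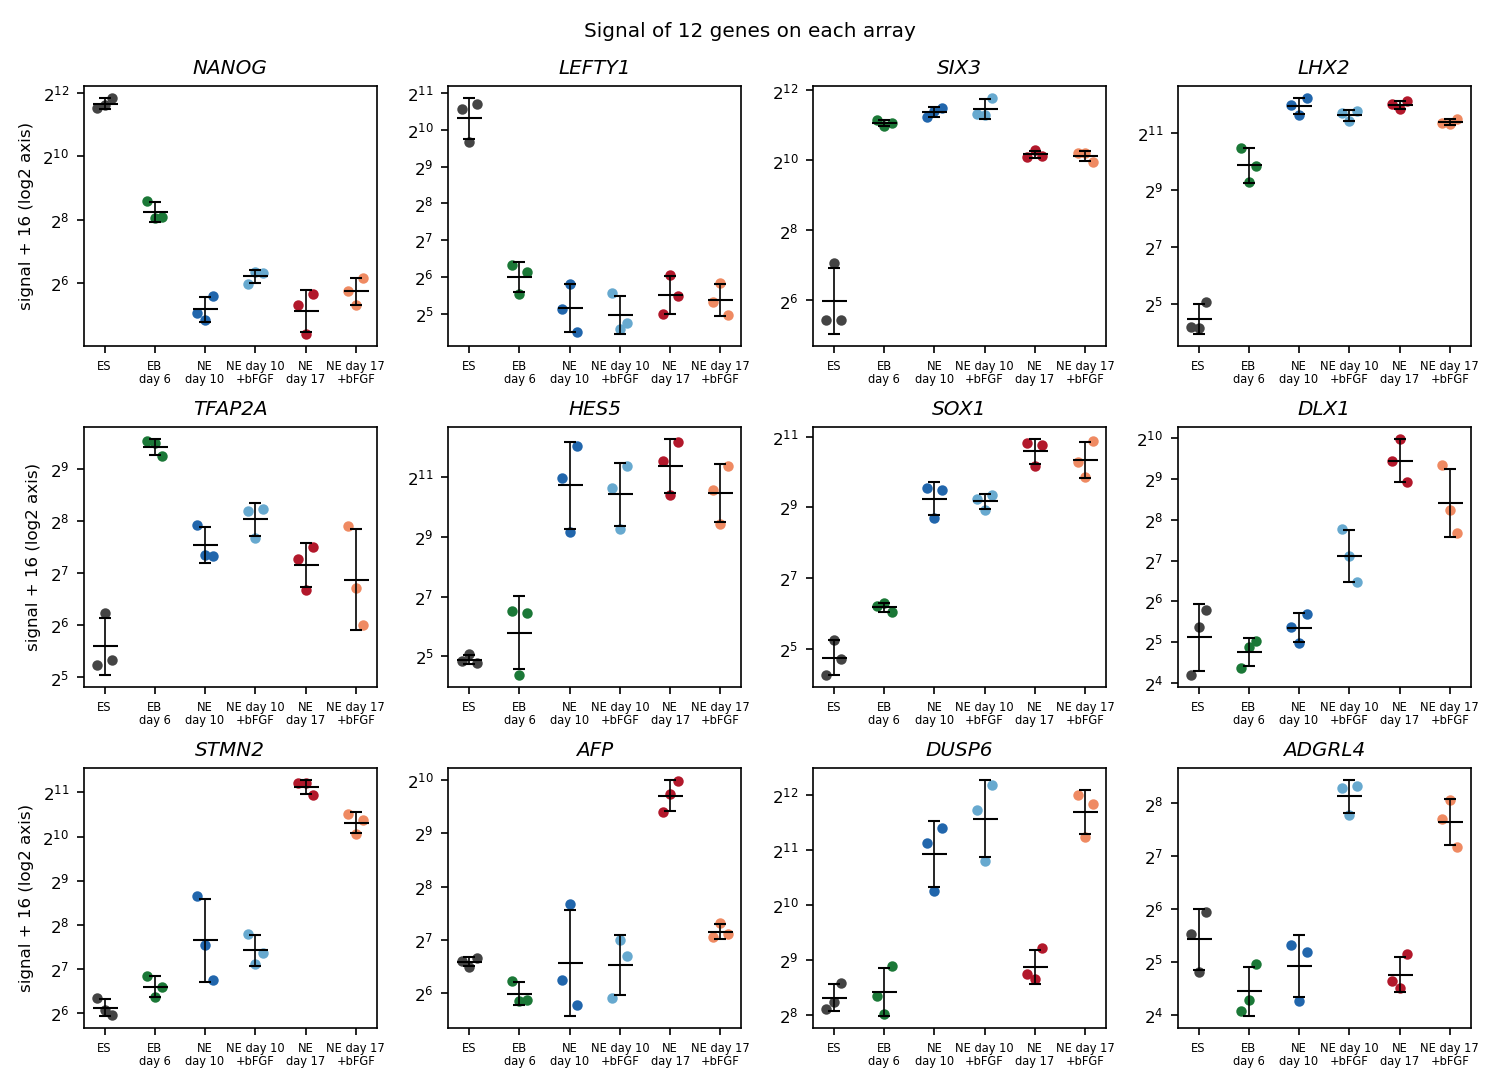
Signals of 12 genes on each array. Points are single arrays on a log2 axis of signal + 16, coloured by group, horizontal bars are means and whiskers SDs of the log2 values over 3 pools; NANOG was at 3203 in ES cells and 291 at day 6, and DUSP6 at 460.2 at day 17 without bFGF and 3374 with it.

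The next comparison followed embryoid bodies at day 6 to neuroepithelium at day 10. HES5, a Notch effector of neural progenitors, rose to 2238 ± 1835 against 50.7 ± 39.9 (log2 change 4.93 ± 0.75). SOX1, an early marker of neural progenitors, rose to 612 ± 184 against 56.2 ± 6.15 (3.08 ± 0.31), ZIC1, a zinc finger factor of the dorsal neural tube, to 1189 against 92.3 (3.36 ± 0.49), and FABP7, a fatty acid binding protein of radial glia, to 6654 against 769 (3.02 ± 0.26). CDH1, the epithelial cadherin, fell to 347 ± 89.7 against 3867 ± 507 (-3.44 ± 0.31), and NANOG to 20.9 ± 10.2 against 291 ± 69.2 (-3.07 ± 0.31). In total 1259 genes differed, 737 higher and 522 lower at day 10, of which 901 changed at least 2-fold.

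Other large increases were in ACTA2, smooth muscle actin (3.58), NPPB, a natriuretic peptide (3.95), COL11A1 (3.47) and COL2A1 (3.40), fibrillar collagens, EMP1 (3.72), NCALD, a neuronal calcium sensor (3.33), and EYA4, a transcriptional coactivator (3.29). CYP26A1, which degrades retinoic acid, fell (-3.73), with ESRP1, a splicing regulator of epithelial cells (-3.51), SCNN1A, a sodium channel subunit (-3.74), IDO1, a tryptophan-degrading enzyme (-3.27), BIK, a pro-apoptotic protein (-3.23), and ZFP42, a pluripotency marker (-3.22). Probe sets named for POU5F1B (-3.43) and for the pseudogenes POU5F1P3 (-3.44) and POU5F1P4 (-3.54) fell, but these near-identical copies of POU5F1, which had no probe set naming it alone here, cannot be assigned with certainty. The largest adjusted p among these was 0.000868, and the 24 largest changes kept their calls when any 1 array was left out.

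Pluripotency genes fell further (median log2 change -1.73, adjusted p = 2.72e-24, and adjusted p = 1.37e-05 with an estimated correlation). Here 14 of 19 measured members fell over all genes and 15 adjusted over the list alone, including PRDM14 (-3.04) and KLF4 (-2.84). Surface ectoderm fell (median log2 change -1.12, adjusted p = 9.40e-10, and adjusted p = 0.000232 with an estimated correlation). Of its 14 measured members, 7 fell over all genes and 7 adjusted over the list alone, among them EPCAM (-2.81) and TFAP2A (-1.88). Early neuroectoderm rose (median log2 change 1.53, adjusted p = 3.76e-14, and adjusted p = 0.000727 with an estimated correlation). Among 20 measured members, 14 rose and 0 fell over all genes, against 16 and 1 adjusted over the list alone. Mesenchyme and muscle rose (median log2 change 1.21, adjusted p = 2.79e-07, and adjusted p = 0.00408 with an estimated correlation), with COL1A1 at 1874 against 327, and 8 of 16 measured members rose over all genes and 11 adjusted over the list alone; this list had fallen between ES cells and day 6, and the 2 comparisons share the day 6 arrays.

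At the preset correlation 8 more lists were called. Nodal and activin genes fell as a list, with a median log2 change of -0.85 (adjusted p = 0.000157, and adjusted p = 0.0738 with an estimated correlation). By member, 2 of 7 fell over all genes and 4 adjusted over the list alone, FOXH1 (-2.91) and FST (-1.49). Among the 22 measured neuronal genes, 5 rose and 1 fell over all genes, against 6 and 1 adjusted over the list alone, including MAP2 (1.81). Their median was 0.48, and the list rose with adjusted p = 0.00406, and adjusted p = 0.0785 with an estimated correlation. The neuronal list lost the call without untreated day 10 pool 1 (adjusted p 0.0878). FGF and ERK targets rose as a list, with a median log2 change of 0.88 (adjusted p = 2.49e-05, and adjusted p = 0.132 with an estimated correlation). Singly, 8 of the 19 rose and 1 fell over all genes, against 10 and 2 adjusted over the list alone, with DUSP6 at 2038 against 336 and ETV5 at 552 against 116. Notch pathway genes rose as a list, with a median log2 change of 0.78 (adjusted p = 7.89e-05, and adjusted p = 0.0588 with an estimated correlation). Here 6 of 15 measured members rose and 1 fell over all genes, against 9 and 1 adjusted over the list alone, with HES4 at 274 against 19.4. BMP targets fell as a list, with a median log2 change of -0.28 (adjusted p = 0.0397, and adjusted p = 0.230 with an estimated correlation). Of its 16 measured members, 0 rose and 2 fell over all genes, against 2 and 7 adjusted over the list alone. BMP targets lost the call without day 6 pool 2 (adjusted p 0.0611), day 6 pool 3 (0.0560), untreated day 10 pool 1 (0.0594), untreated day 10 pool 2 (0.0605), untreated day 10 pool 3 (0.0551) or the 4 arrays (0.0582) or after quantile scaling (0.137).

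Among the 13 measured p53 targets, 3 rose over all genes and 3 adjusted over the list alone, with ZMAT3 at 1.35. Their median was 0.32, and the list rose with adjusted p = 0.0397, and adjusted p = 0.1999 with an estimated correlation. p53 targets lost the call without day 6 pool 2 (adjusted p 0.0688), untreated day 10 pool 1 (0.0816), untreated day 10 pool 3 (0.0591) or the 4 arrays (0.0548). Cell cycle genes fell as a list, with a median log2 change of -0.19 (adjusted p = 0.0220, and adjusted p = 0.172 with an estimated correlation). Among 25 measured members, 1 fell over all genes and 1 adjusted over the list alone. The cell cycle list lost the call without untreated day 10 pool 2 (adjusted p 0.205) or the 4 arrays (0.220) or after quantile scaling (0.715). Among the 18 measured extracellular matrix genes, 5 rose and 0 fell over all genes, against 7 and 1 adjusted over the list alone, including COL5A2 (2.53) and NID1 (1.80). Their median was 0.32, and the list rose with adjusted p = 0.0151, and adjusted p = 0.357 with an estimated correlation. Extracellular matrix lost the call without day 6 pool 3 (adjusted p 0.0560) or untreated day 10 pool 1 (0.111).

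The other 15 lists were not called (adjusted p 0.0812 to 0.982). Forebrain and eye field had a median of 0.59 (adjusted p = 0.0812, and 0.0301 after quantile scaling and 0.0207 without the 4 arrays); LHX2 rose to 3991 against 979 and SIX6 to 370.1 against 50.02, while HESX1 fell (-2.89). HHIP and PTCH1, feedback inhibitors of hedgehog signalling in the ventral list, fell (-2.63 and -1.18), with a list median of 0.01 against a mean of -0.31. Retinoic acid genes went both ways, with ALDH1A2 at -3.14 and ALDH1A3 at 2.06 (list median -0.11). The median was positive and the test downward for glia (0.01), mesendoderm (0.14), trophoblast (0.27, mean -0.16) and neural crest (0.01, mean -0.10).

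The median log2 change of all genes was 0.09, and -0.02 after quantile scaling, so the changes of this comparison are read against a median of 0.09 and not of 0. Quantile scaling also moved the split of calls, from 737 higher of 1259 (58.5%) to 598 higher of 1218 (49.1%). The pools lay apart for 1258 of the 1259 genes, and for 23.2% of all genes, where chance gives 10%. Of the 4 arrays with raised low signals 1 lies among the 3 day 10 arrays and 0 at day 6; without them 1137 genes differed, 943 of them among the 1259, and all 1259 kept their sign. The fit of the 2 compared groups called 647 genes, that without pool 2 813, and that of all probe sets 2123 probe sets. Of the genes named here SCNN1A (-1.06), TFAP2A (-0.84) and PTCH1 (-0.45) lost their calls when a gene's probe sets were averaged, and TFAP2A (-1.75) and ZMAT3 (1.23) without pool 2.

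From day 10 to day 17 without added bFGF, neuronal genes rose as a list (adjusted p = 4.33e-20, and adjusted p = 0.000120 with an estimated correlation), while the forebrain and eye field list was not called (adjusted p = 0.642, and adjusted p = 0.799 with an estimated correlation). DLX1 and DLX2, homeobox genes of the ventral forebrain, rose to 719 ± 267 against 25.6 ± 10.1 (log2 change 4.11 ± 0.46) and 776 ± 86.2 against 45.5 ± 41.5. NR2E1, a nuclear receptor of forebrain and retinal progenitors, rose to 616 against 19.5 (4.25 ± 0.30), EMX2, a dorsal forebrain homeobox gene, to 1289.8 against 149.8 (3.11 ± 0.39), and STMN2, a neuronal microtubule regulator, to 2225 ± 241 against 216 ± 152 (3.47 ± 0.35). AFP, a secreted protein of yolk sac and fetal liver, rose to 830.0 ± 169 against 95.97 ± 81.6 (3.14 ± 0.38). HESX1, an early anterior repressor, fell to 43.1 ± 14.1 against 382 ± 169.6 (-2.70 ± 0.32), and DUSP6, a phosphatase induced by ERK signalling, to 460.2 ± 106 against 2038 ± 755 (-2.05 ± 0.36). In total 393 genes differed, 287 higher and 106 lower at day 17, of which 320 changed at least 2-fold.

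Further increases were in PANTR1, a noncoding RNA (4.79), its neighbour POU3F3, a neural POU factor (3.95), the probe set annotated to DLX6-AS1 (4.04), DCC, a netrin receptor (3.42), ABAT, which degrades GABA (3.24), and TTR, a carrier of thyroid hormone made by liver, yolk sac and choroid plexus (3.27). Of the named increases EMX2 (3.27), TTR (4.01) and APOB (2.26) lost their calls with a pseudocount of 1. PAMR1 (-3.52), PPP2R2B (-2.11), RHOH (-2.09), ROR2, a Wnt receptor (-1.88), GPC3, a glypican (-1.78), and IRS4 (-1.74) fell. Of the 24 largest changes, L1TD1, an RNA-binding protein of pluripotent cells (185 against 909.7), and CLDN11, a tight junction protein (-1.90), lost their calls without the 4 arrays (adjusted p 0.336 and 0.0864) and without single pools: both without untreated day 10 pool 1 or any untreated day 17 pool, L1TD1 also without untreated day 10 pool 2, and CLDN11 also without untreated day 10 pool 3, with log2 changes in those of the fits without 1 pool in which the call was lost of -1.60 to -2.20 for L1TD1 and -1.50 to -2.06 for CLDN11. Without the 4 arrays these changes were -1.68 and -2.16, and with a pseudocount of 1, where both calls were also lost, -2.09 and -2.19; L1TD1 lost its call too when its probe sets were averaged (-1.87). Without pool 2 the call of ROR2 (-1.64) was lost, as was that of DNMT3B (-1.27).

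The median log2 change of neuronal genes was 0.97. By member, 9 of 22 rose over all genes and 14 adjusted over the list alone, including ELAVL3 (2.59) and DCX (2.25). Glial genes rose (median log2 change 0.45, adjusted p = 0.00233, and adjusted p = 0.0357 with an estimated correlation). Singly, 3 of the 13 rose and 0 fell over all genes, against 4 and 1 adjusted over the list alone. Ventral neural tube rose (median log2 change 0.29, adjusted p = 0.00229, and adjusted p = 0.0357 with an estimated correlation), led by NKX2-1, a hypothalamic and ventral forebrain factor (130.4 against 2.49, 2.88), and 2 of 12 measured members rose over all genes and 4 adjusted over the list alone. Endoderm rose (median log2 change 0.51, adjusted p = 5.30e-07, and adjusted p = 0.0249 with an estimated correlation). Here 4 of 13 measured members rose over all genes and 6 adjusted over the list alone; the 4 were AFP, TTR, APOA2 (2.49) and APOB (1.85), of which APOA2 lost its call without untreated day 17 pool 3 (2.15) and APOB without untreated day 10 pool 3 (1.58). Surface ectoderm fell (median log2 change -0.50, adjusted p = 0.00308, and adjusted p = 0.0249 with an estimated correlation), with KRT19 at 338 against 667, and 0 of 14 measured members rose and 0 fell over all genes, against 1 and 2 adjusted over the list alone.

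Pluripotency fell again (median log2 change -0.36, adjusted p = 2.26e-07, and adjusted p = 0.00297 with an estimated correlation). Of its 19 measured members, 5 fell over all genes and 7 adjusted over the list alone, including DNMT3B (494 against 1232, -1.29). Mesenchyme and muscle rose (median log2 change 0.65, adjusted p = 0.000262, and adjusted p = 0.0249 with an estimated correlation), with COL3A1 at 3147 against 763 and POSTN at 309 against 96.8, and 1 of 16 measured members rose and 0 fell over all genes, against 8 and 1 adjusted over the list alone. p53 targets rose (median log2 change 0.40, adjusted p = 0.000262, and adjusted p = 0.0249 with an estimated correlation), with CDKN1A at 611 against 216, and 0 of 13 measured members passed the test, over all genes or adjusted over the list alone.

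Among lists called at the preset correlation alone, FGF and ERK targets fell as a list, with a median log2 change of -0.31 (adjusted p = 0.00338, and adjusted p = 0.222 with an estimated correlation). Among 19 measured members, 0 rose and 3 fell over all genes, against 1 and 8 adjusted over the list alone, with SPRY1 at -1.56. FGF and ERK targets lost the call without untreated day 10 pool 1 (adjusted p 0.0742) or untreated day 17 pool 2 (0.182). Notch pathway genes rose as a list, with a median log2 change of 0.56 (adjusted p = 0.00308, and adjusted p = 0.113 with an estimated correlation). By member, 1 of 15 rose over all genes and 5 adjusted over the list alone, with HEY1 at 1.70. Notch lost the call without untreated day 10 pool 2 (adjusted p 0.0738). Wnt targets rose as a list, with a median log2 change of 0.28 (adjusted p = 0.00303, and adjusted p = 0.0855 with an estimated correlation). Singly, 2 of the 15 rose and 0 fell over all genes, against 5 and 1 adjusted over the list alone, with APCDD1 at 1.29. Among the 20 measured early neuroectoderm genes, 4 rose and 0 fell over all genes, against 5 and 2 adjusted over the list alone. Their median was 0.17, and the list rose with adjusted p = 0.0173, and adjusted p = 0.185 with an estimated correlation. Early neuroectoderm lost the call without untreated day 10 pool 2 (adjusted p 0.279), untreated day 17 pool 3 (0.130) or the 4 arrays (0.0563). Dorsal neural tube genes rose as a list, with a median log2 change of 0.39 (adjusted p = 0.0203, and adjusted p = 0.222 with an estimated correlation). Here 0 of 13 measured members rose over all genes and 1 adjusted over the list alone. Dorsal neural tube lost the call without untreated day 10 pool 3 (adjusted p 0.178), untreated day 17 pool 1 (0.0741) or untreated day 17 pool 3 (0.223).

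Among the 16 measured BMP targets, 1 rose over all genes and 4 adjusted over the list alone. Their median was 0.16, and the list rose with adjusted p = 0.0440, and adjusted p = 0.222 with an estimated correlation. BMP targets lost the call without untreated day 10 pool 1 (adjusted p 0.0513), untreated day 10 pool 2 (0.0962), untreated day 10 pool 3 (0.0590), untreated day 17 pool 1 (0.0741) or untreated day 17 pool 3 (0.494), with the pool number as a block (0.0778) or after quantile scaling (0.0795). Cholesterol synthesis genes rose as a list, with a median log2 change of 0.14 (adjusted p = 0.0479, and adjusted p = 0.222 with an estimated correlation). Of its 15 measured members, 0 passed the test, over all genes or adjusted over the list alone. Cholesterol synthesis lost the call without untreated day 10 pool 1 (adjusted p 0.0814), untreated day 10 pool 2 (0.227), untreated day 17 pool 1 (0.251) or untreated day 17 pool 3 (0.262). Among the 18 measured extracellular matrix genes, 2 rose over all genes and 4 adjusted over the list alone. Their median was 0.41, and the list rose with adjusted p = 0.0203, and adjusted p = 0.380 with an estimated correlation. Extracellular matrix lost the call without untreated day 10 pool 3 (adjusted p 0.166), untreated day 17 pool 1 (0.0741) or untreated day 17 pool 3 (0.130). Ribosomal protein genes, the control list, fell as a list, with a median log2 change of -0.20 (adjusted p = 0.0140, and adjusted p = 0.577 with an estimated correlation). Among 20 measured members, 0 passed the test, over all genes or adjusted over the list alone. This control lost the call without untreated day 10 pool 3 (adjusted p 0.970), untreated day 17 pool 1 (0.222) or untreated day 17 pool 2 (0.294) or after quantile scaling (0.918).

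Of the 10 lists that were not called (adjusted p 0.0768 to 0.874), midbrain and hindbrain had a median of -0.30, neural crest -0.16 and cell cycle -0.10. Signs differed for forebrain and eye field (median -0.02, mean 0.37, test upward), Nodal and activin (-0.11, 0.01, upward), retinoic acid (-0.19, 0.01, downward) and hypoxia (0.02, -0.02, downward). In the retinoic acid list CYP26A1 fell (-1.43, a call lost without pool 2, at -1.43) and RDH10 rose (1.38). The pools lay apart for all 393 genes, and for 13.6% of all genes, where chance gives 10%. The count was 754 (519 higher, 235 lower) with the pool number as a block and 229 without the 4 arrays, where 182 of the 393 kept their calls and all 393 their sign. It was 261 without untreated day 10 pool 1, 219 without its pool 3, and 206, 257 and 254 without untreated day 17 pools 1, 2 and 3. A fit of the compared groups alone called 34 genes, one with a pseudocount of 1 called 226, and one without pool 2 called 182.

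**Figure D3:**
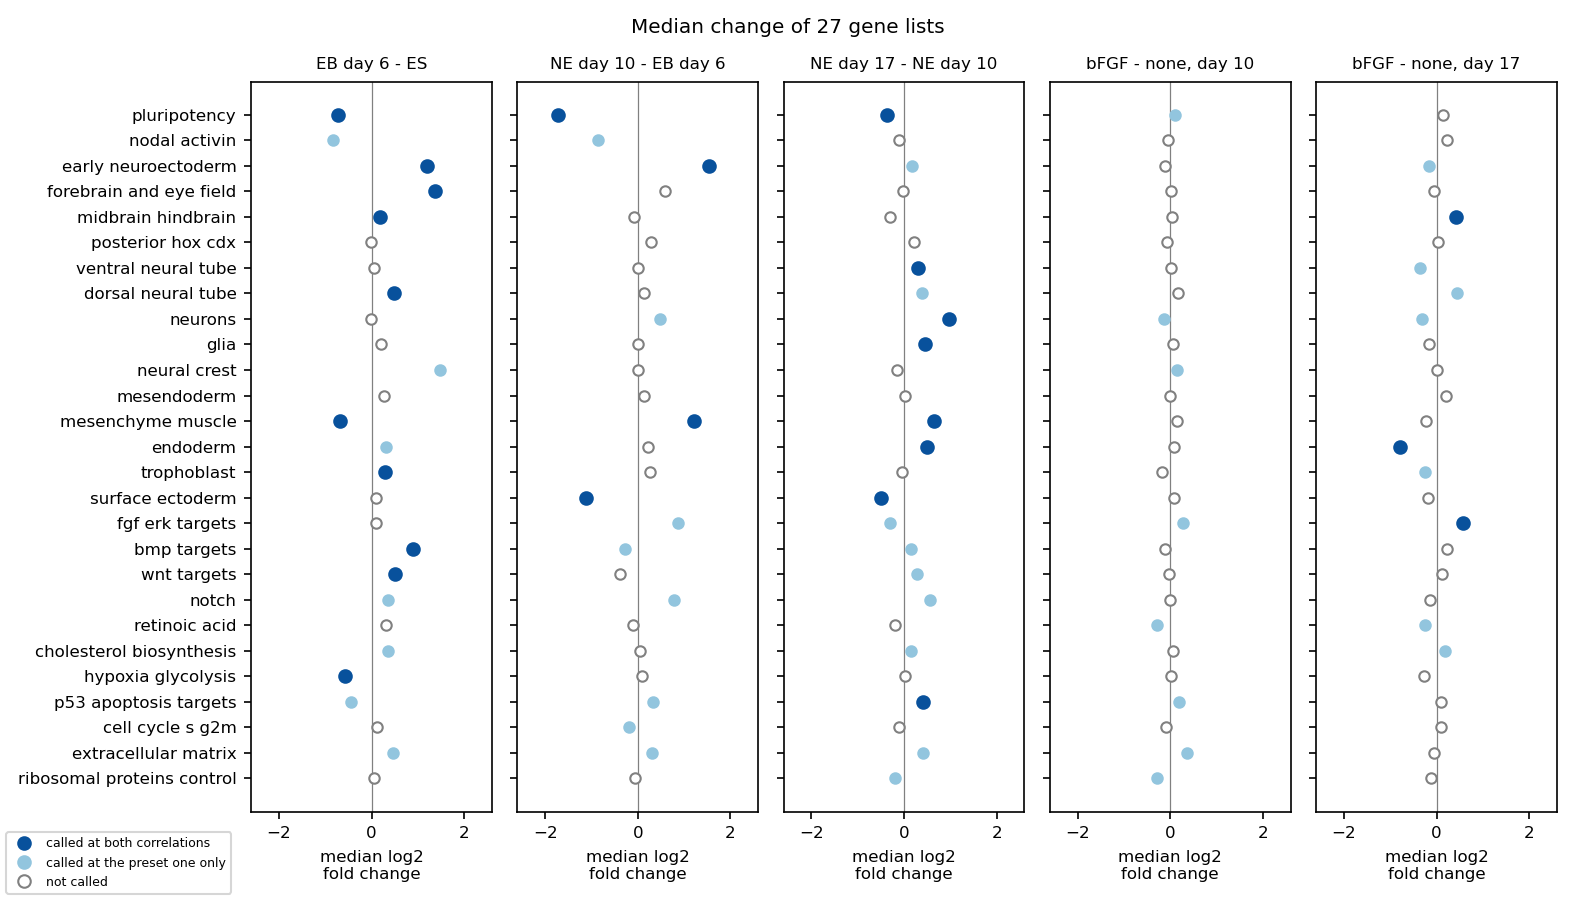
Median log2 change of each of the 27 gene lists in the 5 comparisons of groups. Each point is the median over a list's measured members, dark blue where the list was called with the preset and with an estimated correlation, light blue where it was called with the preset correlation alone, and open where it was not called; pluripotency lies at -0.73, -1.73 and -0.36 in the 3 comparisons of stages.

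With bFGF from day 6 to day 10, 17 genes differed at day 10, 16 higher and 1 lower. ADGRL4, an adhesion receptor of endothelial cells, rose to 269.7 ± 57.4 against 15.9 ± 11.2 (log2 change 3.21 ± 0.36, adjusted p = 0.00167), DKK2, a secreted modulator of Wnt signalling, to 152 ± 58.8 against 18.9 ± 7.36 (2.23 ± 0.28, adjusted p = 0.00388), and PHLDA2, an imprinted growth regulator, to 585 ± 196 against 114 ± 14.01 (2.16 ± 0.25, adjusted p = 0.00167). TM4SF1 (3.21), MMP7, a matrix metalloproteinase (2.89), LOX, which crosslinks collagen (2.68), COL8A1 (2.21), NT5E, an ectonucleotidase (2.07), WNK4, a kinase (1.83), EDN1, a vasoactive peptide (1.80), PLAU, the urokinase (1.49), and SGK1, a kinase (1.38), rose as well. HSD3B1, an enzyme of steroid synthesis, was the gene that fell (6.36 ± 3.79 against 71.2 ± 38.2, -1.89 ± 0.29).

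Among the 19 measured FGF and ERK targets, 1 rose over all genes and 3 adjusted over the list alone; the member that rose was PHLDA1 (360.0 against 141, 1.22), whose call was lost without the 4 arrays (1.40), without untreated day 10 pool 1 (1.22), 2 (1.21) or 3 (1.24) and without bFGF day 10 pool 1 (1.26) or 3 (1.01). IER3 was at 1599 against 605 (1.35). The list rose (median log2 change 0.26, adjusted p = 1.70e-07, and adjusted p = 0.182 with an estimated correlation). No list was called with an estimated correlation, and 7 others were called at the preset one. Extracellular matrix genes rose as a list, with a median log2 change of 0.36 (adjusted p = 1.45e-05, and adjusted p = 0.276 with an estimated correlation). By member, 0 of 18 passed the test, over all genes or adjusted over the list alone, with FN1 at 3918 against 2320.2. The ribosomal control fell (median log2 change -0.28, adjusted p = 0.000252, and adjusted p = 0.632 with an estimated correlation). Singly, 0 of the 20 passed the test, over all genes or adjusted over the list alone. The call was lost without untreated day 10 pool 3 (adjusted p 0.845) or after quantile scaling (0.810, median -0.00, test upward). With the control called here and from day 10 to day 17, calls at the preset correlation alone are uncertain. Among the 19 measured pluripotency genes, 0 passed the test, over all genes or adjusted over the list alone, with NANOG at 58.6 against 20.9. Their median was 0.10, and the list rose with adjusted p = 0.0390, and adjusted p = 0.276 with an estimated correlation. Pluripotency lost the call without untreated day 10 pool 1 (adjusted p 0.159), untreated day 10 pool 2 (0.0697), untreated day 10 pool 3 (0.162), bFGF day 10 pool 2 (0.169), bFGF day 10 pool 3 (0.0836) or the 4 arrays (0.109) or after quantile scaling (0.0530). Neuronal genes fell as a list, with a median log2 change of -0.14 (adjusted p = 0.0390, and adjusted p = 0.276 with an estimated correlation). Here 0 of 22 measured members passed the test, over all genes or adjusted over the list alone. The neuronal list lost the call without untreated day 10 pool 1 (adjusted p 0.961), untreated day 10 pool 2 (0.0672), bFGF day 10 pool 1 (0.124), bFGF day 10 pool 2 (0.148) or the 4 arrays (0.0627) or after quantile scaling (0.0530).

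Neural crest genes rose as a list, with a median log2 change of 0.15 (adjusted p = 0.0301, and adjusted p = 0.448 with an estimated correlation). Of its 11 measured members, 0 rose over all genes and 1 adjusted over the list alone, with TWIST1 at 179 against 42.3. Neural crest lost the call without untreated day 10 pool 2 (adjusted p 0.368), untreated day 10 pool 3 (0.129), bFGF day 10 pool 1 (0.298) or the 4 arrays (0.260). Among the 10 measured retinoic acid genes, 0 passed the test, over all genes or adjusted over the list alone, with ALDH1A1 at 42.8 against 127. Their median was -0.28, and the list fell with adjusted p = 0.0301, and adjusted p = 0.182 with an estimated correlation. Retinoic acid lost the call without untreated day 10 pool 2 (adjusted p 0.0871), untreated day 10 pool 3 (0.173), bFGF day 10 pool 1 (0.144), bFGF day 10 pool 2 (0.0608) or the 4 arrays (0.0677). p53 targets rose as a list, with a median log2 change of 0.18 (adjusted p = 0.0417, and adjusted p = 0.276 with an estimated correlation). Among 13 measured members, 0 passed the test, over all genes or adjusted over the list alone. p53 targets lost the call without untreated day 10 pool 1 (adjusted p 0.159), untreated day 10 pool 2 (0.189), untreated day 10 pool 3 (0.0650), bFGF day 10 pool 3 (0.464) or the 4 arrays (0.0668) or after quantile scaling (0.0794).

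The other 19 lists were not called (adjusted p 0.173 to 0.924), among them endoderm (median 0.07), forebrain and eye field (0.01) and midbrain and hindbrain (0.05). Signs differed for posterior HOX and CDX (median -0.07, mean 0.02, test upward), mesendoderm (-0.01, 0.00, upward), Wnt targets (-0.02, 0.06, upward), Notch (-0.01, 0.03, upward) and cell cycle (-0.09, 0.01, downward).

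The pools lay apart for all 17 genes, but for 6.11% of all genes, under the 10% of chance, and 613 genes had an unadjusted p under 0.05 where chance gives 989, against 1073 with the pool number as a block. The count was 34 (29 higher, 5 lower) with the pool number as a block, and 4 without the 4 arrays: ADGRL4, MMP7, DKK2 and PHLDA2. It was 3, 8 and 6 without untreated day 10 pools 1, 2 and 3, and 4 and 3 without bFGF day 10 pools 1 and 3. A fit of the compared groups alone gave 0 (limma; 501 genes at an unadjusted p under 0.05), one with a pseudocount of 1 called 2, one on the mean of a gene's probe sets 10, and one without pool 2 called 4. Of the 13 largest changes ADGRL4, DKK2 and PHLDA2 kept their calls without any 1 array, while 10, 5 and 7 were lost without untreated day 10 pools 1, 2 and 3, and 9, 5 and 10 without bFGF day 10 pools 1, 2 and 3. With a pseudocount of 1 all of the 13 but PHLDA2 lost their calls, among them ADGRL4 (4.35) and DKK2 (2.93). With a gene's probe sets averaged those of DKK2 (0.93), COL8A1 (1.10), PHLDA2 (0.75), NT5E (0.83), WNK4 (1.36), EDN1 (1.05) and HSD3B1 (-1.06) were lost, and without pool 2 those of PHLDA2 (2.20) and of the others of the 13 except ADGRL4, MMP7 and DKK2. After quantile scaling WNK4, PLAU and HSD3B1 lost theirs, WNK4 also with a pseudocount of 64 (0.93) and with a trended and robust variance prior. PHLDA1, named as an FGF and ERK target, lost its call with a pseudocount of 1 (1.31), with its probe sets averaged (0.91) and without pool 2 (1.40).

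With bFGF from day 6 to day 17, feedback genes of FGF signalling were higher at day 17. DUSP6 was at 3374 ± 874 against 460.2 ± 106 (log2 change 2.82 ± 0.36, adjusted p = 0.00231), SPRY1, an inhibitor of receptor tyrosine kinase signalling, at 1640.3 ± 245 against 302 ± 73.4 (2.40 ± 0.26), and FGF18, an FGF ligand, at 440.2 against 83.7 (2.14 ± 0.28). EN2, a homeobox gene of the midbrain and hindbrain boundary, rose to 92.8 ± 31.8 against 17.1 ± 8.87 (1.71 ± 0.24). AFP fell to 127 ± 13.7 against 830.0 ± 169 (-2.55 ± 0.38), and CRYAB, a small heat shock protein of lens and muscle, to 54.6 ± 20.6 against 402 ± 143 (-2.55 ± 0.34). In total 67 genes differed, 36 higher and 31 lower with bFGF, of which 65 changed at least 2-fold.

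ADGRL4 (2.89), NT5E (2.20), DKK2 (2.04) and LGI1, a secreted neuronal protein (2.20), also rose. DAPL1 (17.1 against 427, -3.77), GABRP, a GABA receptor subunit (-2.89), BHMT, which remethylates homocysteine (-2.88), and HSD17B2, a steroid dehydrogenase (-2.78), fell. These and the genes named before kept their calls when any 1 array was left out. Calls that did not hold in each such fit were those of SPRY4 (2.06), the probe set annotated to SPRY4-IT1, which overlaps it (2.36), ETV4 (2.12), CPNE4 (1.93), PRRX1 (2.18), ALDH1A1 (49.8 against 534, -2.97), CYP1B1 (-2.42), SST (-2.31), FGA (-2.17), APOB (-1.99) and NR2E1 (-1.98). Of the 24 largest changes 5, 6 and 8 lost their calls without untreated day 17 pools 1, 2 and 3, and 10, 5 and 8 without bFGF day 17 pools 1, 2 and 3. Without the 4 arrays PRRX1 (adjusted p 0.0732), FGA (0.239) and APOB (0.0509) lost theirs, and after quantile scaling ETV4 and FGA. With a pseudocount of 1 the calls of EN2, ADGRL4, NT5E, DKK2 and HSD17B2 were lost too, as were those of PRRX1, ETV4, CPNE4, ALDH1A1, CYP1B1, SST, FGA, APOB and NR2E1; SST also lost its call with a pseudocount of 64 (-1.84). When a gene's probe sets were averaged the calls of NT5E (0.75), DKK2 (1.31), SPRY4-IT1 (1.46) and FGA (-0.87) were lost. Without pool 2 those of DKK2 (1.71), GABRP (-2.71) and HSD17B2 (-2.68) were lost, as were those of SPRY4, ETV4, CPNE4, PRRX1, SST, FGA, APOB and NR2E1.

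FGF and ERK targets rose (median log2 change 0.58, adjusted p = 1.94e-20, and adjusted p = 0.00524 with an estimated correlation). By member, 8 of 19 rose over all genes and 10 adjusted over the list alone. Midbrain and hindbrain rose (median log2 change 0.42, adjusted p = 8.04e-07, and adjusted p = 0.00524 with an estimated correlation). Singly, 2 of the 17 rose over all genes and 4 adjusted over the list alone; besides EN2 the member that rose was PAX5 (114 against 25.3, 1.79), whose call was lost with a pseudocount of 1 (2.59), with its probe sets averaged (0.89), without pool 2 (2.14), without untreated day 17 pool 1 (1.86) or 3 (1.36) and without bFGF day 17 pool 1 (1.78), 2 (1.78) or 3 (1.80). GBX2 was at 38.05 against 3.65 and FGF17 at 130.2 against 37.8. Endoderm fell (median log2 change -0.79, adjusted p = 1.48e-06, and adjusted p = 0.0372 with an estimated correlation). Here 2 of 13 measured members fell over all genes and 6 adjusted over the list alone, with TTR at 101 against 389 (-1.83) and FGB at 22.98 against 98.9 (-1.65). AFP, APOB, NR2E1 and DUSP6 had changed in the opposite direction from day 10 to day 17 without bFGF, and the 2 comparisons share the untreated day 17 arrays, so chance values of those arrays move both.

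Called at the preset correlation alone were 7 lists. Dorsal neural tube genes rose as a list, with a median log2 change of 0.45 (adjusted p = 8.93e-05, and adjusted p = 0.0811 with an estimated correlation). Of its 13 measured members, 1 rose over all genes and 1 adjusted over the list alone, with PAX7 at 149 against 31.5 (1.77) and MSX1 at 411 against 207. PAX7 lost its call with a pseudocount of 1 (2.19), with its probe sets averaged (0.76), and without pool 2 or the 4 arrays (1.77), untreated day 17 pool 2 (1.61) or bFGF day 17 pool 1 (1.503). Dorsal neural tube lost the call without untreated day 17 pool 2 (adjusted p 0.0676) or the 4 arrays (0.123). Among the 12 measured ventral neural tube genes, 0 fell over all genes and 1 adjusted over the list alone, with NKX2-1 at 65.4 against 130.4. Their median was -0.37, and the list fell with adjusted p = 0.0167, and adjusted p = 0.0984 with an estimated correlation. Ventral neural tube lost the call without untreated day 17 pool 1 (adjusted p 0.0502), untreated day 17 pool 3 (0.0719) or bFGF day 17 pool 2 (0.0895). Neuronal genes fell as a list, with a median log2 change of -0.31 (adjusted p = 0.0108, and adjusted p = 0.0984 with an estimated correlation). Among 22 measured members, 0 rose over all genes and 1 adjusted over the list alone, with STMN2 at 1268 against 2225. The neuronal list lost the call without untreated day 17 pool 1 (adjusted p 0.133) or bFGF day 17 pool 2 (0.161). Among the 20 measured early neuroectoderm genes, 0 rose and 0 fell over all genes, against 1 and 5 adjusted over the list alone, with SOX3 at 867 against 1907. Their median was -0.16, and the list fell with adjusted p = 0.0167, and adjusted p = 0.163 with an estimated correlation. Early neuroectoderm lost the call without untreated day 17 pool 1 (adjusted p 0.0922), untreated day 17 pool 3 (0.161) or bFGF day 17 pool 2 (0.282).

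Retinoic acid genes fell as a list, with a median log2 change of -0.26 (adjusted p = 0.0167, and adjusted p = 0.0763 with an estimated correlation). By member, 0 of 10 rose and 2 fell over all genes, against 1 and 2 adjusted over the list alone, the latter ALDH1A1 and ALDH1A3 (-1.92). ALDH1A3 lost its call with a pseudocount of 1 (-2.13), with its probe sets averaged (-0.83), and without pool 2 or the 4 arrays (-1.58), untreated day 17 pool 2 (-1.81) or 3 (-1.93) or bFGF day 17 pool 2 (-1.68), and ALDH1A1 without any 1 of the 6 arrays. Retinoic acid lost the call without untreated day 17 pool 3 (adjusted p 0.0728) or bFGF day 17 pool 2 (0.266). Among the 15 measured cholesterol synthesis genes, 0 passed the test, over all genes or adjusted over the list alone. Their median was 0.19, and the list rose with adjusted p = 0.0167, and adjusted p = 0.136 with an estimated correlation. Cholesterol synthesis lost the call without untreated day 17 pool 2 (adjusted p 0.605), bFGF day 17 pool 3 (0.212) or the 4 arrays (0.135). Trophoblast genes fell as a list, with a median log2 change of -0.26 (adjusted p = 0.0167, and adjusted p = 0.0984 with an estimated correlation). Singly, 0 of the 13 fell over all genes and 1 adjusted over the list alone, with EPAS1 at 82.01 against 243.

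The remaining 17 lists were not called (adjusted p 0.0537 to 0.781). Surface ectoderm had a median of -0.19 (adjusted p = 0.0537, and 0.0444 after quantile scaling), and forebrain and eye field -0.04, with SIX6 at 123 against 347. ADM, in the hypoxia list, rose (449.8 against 144, 1.54, a call lost without pool 2, at 1.68), with a list median of -0.26. Signs differed for posterior HOX and CDX (median 0.02, mean -0.03, test downward), extracellular matrix (-0.06, 0.07, upward) and cell cycle (0.09, -0.05, upward); quantile scaling turned the test direction of the first 2. The pools lay apart for all 67 genes, and for 9.03% of all genes, where chance gives 10%, and 980 genes had an unadjusted p under 0.05 where chance gives 989, against 1702 with the pool number as a block. The count was 120 (58 higher, 62 lower) with the pool number as a block, 45 without the 4 arrays, where 36 of the 67 kept their calls, 41, 33 and 32 without untreated day 17 pools 1, 2 and 3, and 22 and 35 without bFGF day 17 pools 1 and 3. A fit of the compared groups alone gave 0 (limma; 808 genes at an unadjusted p under 0.05), one with a pseudocount of 1 called 20, and one without pool 2 called 22.

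The effects of bFGF at the 2 days were then compared. They share no array, but the fit gives each gene 1 spread for both. The day goes with the length of treatment and with the labelled dose, so these cannot be told apart from stage. For 0 of 19775 genes did the effect differ between day 17 and day 10 (limma, smallest adjusted p 0.422, for SPRY1), and 631 had an unadjusted p under 0.05 where chance gives 989, against 1317 with the pool number as a block. The count was 1 with the pool number as a block or as a random effect, with a pseudocount of 64, with the array set as a term, and without untreated day 10 pool 2, and 0 in the other fits. Across genes, which are not independent replicates, the log2 changes at the 2 days correlated with Pearson's r of 0.0785 and Spearman's rho of -0.0151; r was -0.00273 without untreated day 10 pool 2, 0.153 without its pool 3, 0.0342 without bFGF day 10 pool 1 and 0.0248 without bFGF day 17 pool 1. 7 genes were higher with bFGF at both days and 0 lower at both. Independent lists give 0.0291, but the shared spread ties these. The 7 were ADGRL4, DKK2, LOX, NT5E, PHLDA1, PHLDA2 and TM4SF18. The last, named after its values were seen, changed by 1.32 at day 10 and 1.54 at day 17. Of the 17 genes called at day 10, 16 had the same sign at day 17, and of the 67 called at day 17, 62 had the same sign at day 10. At the preset correlation 6 lists differed between the days, and none did with an estimated correlation (smallest adjusted p 0.126); among the others forebrain and eye field had adjusted p = 0.0865, and 0.0493 after quantile scaling, and the cell cycle list a median of 0.19 against a mean of -0.06.

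**Figure D4:**
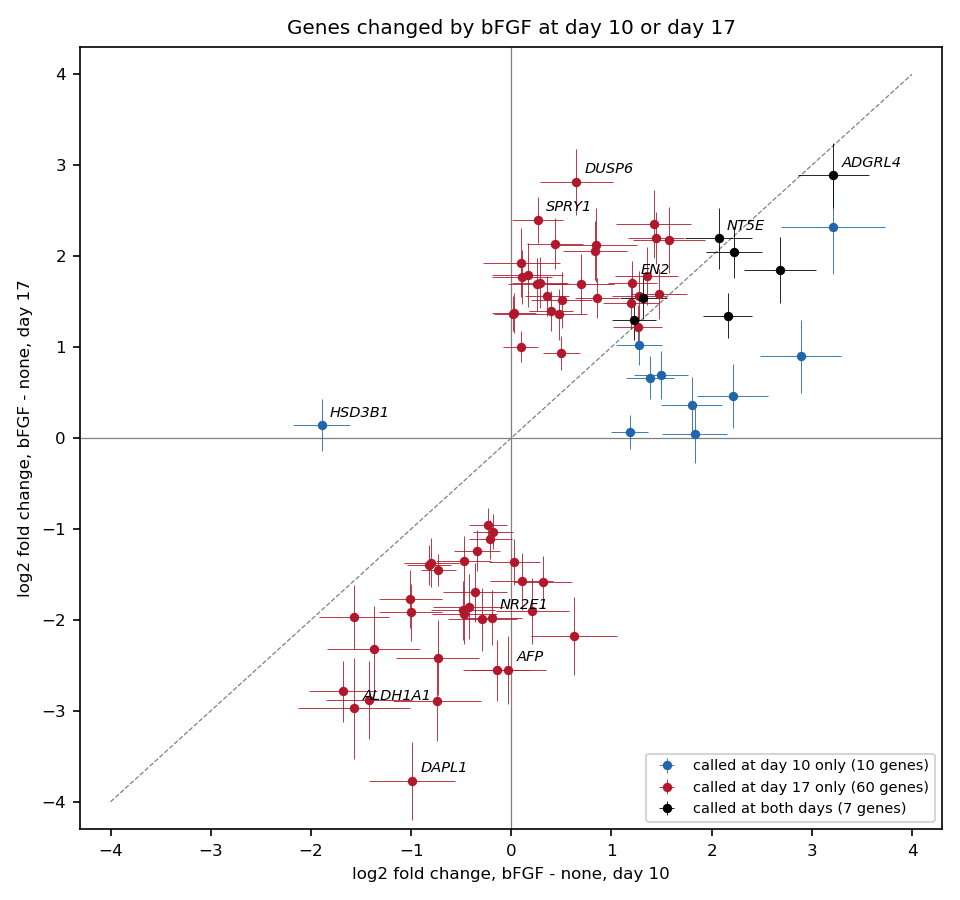
Genes called with bFGF at day 10 or day 17. Each of 77 points is 1 gene, with its log2 change at day 10 on the horizontal and at day 17 on the vertical axis and bars of 1 standard error; 10 were called at day 10 alone, 60 at day 17 alone and 7 at both, where the difference between the days passed the test for none of them.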

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

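The tests of what lies behind the FGF and ERK difference, and those without the 4 arrays or single arrays for lists, were chosen after the result was seen; those on other groupings of the arrays were set beforehand. The effect of bFGF differed by day for 6 gene lists at the preset correlation and for none with an estimated one. Endoderm had a median difference of -0.69 (median changes 0.07 at day 10 and -0.79 at day 17, 3 of 13 members positive, adjusted p = 2.09e-05, and adjusted p = 0.126 with an estimated correlation). FGF and ERK targets had one of 0.43 (0.26 and 0.58, 13 of 19 positive, adjusted p = 3.90e-05, and adjusted p = 0.204 with an estimated correlation). For midbrain and hindbrain it was 0.54 (0.05 and 0.42, 13 of 17 positive, adjusted p = 0.00942, and adjusted p = 0.126 with an estimated correlation). Midbrain and hindbrain lost the call without untreated day 10 pool 2 (adjusted p 0.0654) or bFGF day 17 pool 1 (0.1003).

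Extracellular matrix genes had a median difference of -0.38 (0.36 at day 10 and -0.06 at day 17, 5 of 18 positive, adjusted p = 0.0188, and adjusted p = 0.540 with an estimated correlation). The list lost the call without untreated day 10 pool 2 (adjusted p 0.0654), untreated day 10 pool 3 (0.0889), untreated day 17 pool 1 (0.101), untreated day 17 pool 3 (0.0843), bFGF day 10 pool 1 (0.0606), bFGF day 10 pool 3 (0.0775), bFGF day 17 pool 2 (0.0795) or bFGF day 17 pool 3 (0.117). For ventral neural tube the difference was -0.38 (0.01 and -0.37, 2 of 12 positive, adjusted p = 0.0336, and adjusted p = 0.204 with an estimated correlation). Ventral neural tube lost the call without untreated day 10 pool 1 (adjusted p 0.234), untreated day 10 pool 2 (0.0698), untreated day 17 pool 1 (0.0690), untreated day 17 pool 3 (0.0843), bFGF day 10 pool 1 (0.0606), bFGF day 10 pool 2 (0.0967), bFGF day 17 pool 2 (0.0795) or the 4 arrays (0.0806), with the pool number as a block (0.0817) or after quantile scaling (0.0634). For dorsal neural tube it was 0.45 (0.16 and 0.45, 9 of 13 positive, adjusted p = 0.0336, and adjusted p = 0.430 with an estimated correlation). Dorsal neural tube lost the call without untreated day 10 pool 1 (adjusted p 0.230), untreated day 10 pool 2 (0.0876), untreated day 17 pool 2 (0.537), bFGF day 10 pool 2 (0.110), bFGF day 10 pool 3 (0.0574), bFGF day 17 pool 1 (0.192), bFGF day 17 pool 2 (0.0720) or the 4 arrays (0.850), with the pool number as a block (0.118) or after quantile scaling (0.0826).

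FGF and ERK targets had a larger effect of bFGF at day 17 than at day 10 at the preset correlation alone (adjusted p = 3.90e-05). Saturated signals at day 10 are argued against by the highest member without bFGF, at 17.2% of the lowest array maximum. The 4 arrays with raised low signals stay open, since only the preset call was tested without them (kept, adjusted p 0.00181). Members moving together by chance remain a candidate explanation, because of the adjusted p of 0.204 with an estimated correlation. A fall of the list without bFGF from day 10 to day 17 also stays open (median -0.31 without bFGF against 0.13 with it; adjusted p = 0.222 with an estimated correlation). bFGF acting differently by day was not separable from these, and the untreated day 10 and day 17 arrays enter both the fall and the difference.

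Of the 10 splits of the 6 arrays of a comparison into 3 and 3, 1 gave as many genes as the real one, itself, so the share cannot go under 0.05. The real counts and the highest of the other splits were 762 and 0 for day 6 against ES cells, 1259 and 0 for day 10 against day 6, 393 and 2 for day 17 against day 10, 17 and 1 for bFGF at day 10, and 67 and 0 for bFGF at day 17. In the paired comparisons 4 splits, the real one included, part all 3 pairs and 6 part 1 pair, and the 2 and the 1 came from splits of the second kind. For the difference between the days 100 of 100 drawn splits of the 12 arrays gave at least the real count of 0, which any split does, so that these splits test nothing. The highest gave 2588, and the cause of that count was not tested.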

How the results depend on the processing

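Tests without pool 2, without the 4 arrays with raised low signals or with them as a term, and the list tests after quantile scaling, without these arrays and without single arrays, were chosen after the data were seen. With the pool number as a replicate block the counts were 1454 for day 6 against ES cells, 2512 for day 10 against day 6, 754 for day 17 against day 10, 34 and 120 for bFGF at day 10 and day 17 and 1 for the difference; as a random block (consensus correlation 0.291) they were 1363, 2300, 754, 38, 122 and 1. Day 10 and day 6 share only pool numbers, with correlations of deviations of 0.0749 to 0.337. The block kept 65 of 70 list calls, lost 5 and gained 1, and changed no other call of a list; all genes called without it were also called with it. With the array set as a term the counts were 1171 for day 6, 645 for day 17, 37 and 102 for bFGF and 1 for the difference. Without the 4 arrays 229 were called for day 17 and 4 for bFGF at day 10, and without pool 2 813 for day 10, 182 for day 17, and 4 and 22 for bFGF. A pseudocount of 1 gave 226 for day 17, 2 for bFGF at day 10 and 20 for bFGF at day 17, and one of 64 gave 1 for the difference. A fit of the compared groups alone, with fewer arrays to estimate the spread, gave 647 for day 10, 34 for day 17 and 0 for bFGF at both days (limma; 501 and 808 genes at an unadjusted p under 0.05). All probe sets gave 2123 for day 10, and the mean of a gene's probe sets 10 for bFGF at day 10. The causes of the other shifts were not tested, and the other counts stayed within 1.5 times. Leaving out 1 array gave 462 to 615 for day 6, 842 to 1033 for day 10, 206 to 311 for day 17, 3 to 13 and 22 to 45 for bFGF at day 10 and day 17, 0 to 1 for the difference, 59 to 73 called lists, and correlations of the bFGF effects of -0.00273 to 0.153. Of 70 called lists 25 were kept with an estimated correlation, 44 with fry (which gained 7), 57 without the 4 arrays (2 gained) and 60 after quantile scaling (3 gained). The ribosomal list turned with bFGF at day 10 after quantile scaling, to an adjusted p of 0.810; the cause was not tested. Of 1841 values of the 109 largest changes 1655 kept direction and side of the threshold, 186 missed the threshold and 0 turned; of 8045 values of other list members 7435 were kept, 346 missed the threshold, 264 newly passed it and 0 turned. Without detection calls, how far low signals stand above background is unknown.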

Other observations

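The tests of left-out pools and arrays, and that of surface ectoderm and mesenchyme as a sign of other cells, were chosen after the result was seen; those on the added lists were set before their results were seen. With bFGF at day 17 several genes expressed in retina or lens were lower than without it. CRB1, a polarity protein of photoreceptors, was at 32.7 ± 13.3 against 175 ± 73.1 (log2 change -1.94 ± 0.32), FOXE3, a lens transcription factor, at 21.1 ± 10.2 against 126 ± 15.7 (-1.96 ± 0.35), and ALDH1A3, which makes retinoic acid in the eye, at 74.8 ± 24.4 against 320 ± 45.4 (-1.92 ± 0.31); CRB1 and FOXE3 were chosen after their values were seen. Their adjusted p were 0.0129, 0.0190 and 0.0110 (limma), with each group of 3 pools. From day 10 to day 17 HTR2C, a serotonin receptor, rose from 95.9 ± 20.5 to 459 ± 28.5 (2.10 ± 0.25), and FGG, a fibrinogen chain, from 7.24 ± 5.93 to 58.7 ± 32.7 (1.63 ± 0.33), with adjusted p of 0.000207 and 0.0160; both were chosen after their values were seen. How the calls of CRB1, FOXE3, HTR2C and FGG depend on the setting is not reported here. The 10 choroid plexus genes without TTR and MSX1, set against bFGF at day 17 after the day 17 result was seen, had a median of -0.08 with a downward test (0.0417 with an estimated correlation and 0.00336 at the preset one, both unadjusted), and 0 of them passed the test singly; KCNJ13 was at 40.7 against 145, ENPP2 at 586 against 1169.7 and HTR2C at 219 against 459, while FOLR1 (2247 against 1706, 0.43), SLC4A5 (0.33), PRLR (0.19) and CLIC6 (0.07) had positive log2 changes.

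The 4 endoderm genes that rose from day 10 to day 17 had a median log2 change of 2.82, and the 4 arrays with raised low signals are argued against by an adjusted p of 0.00652 with an estimated correlation for all 13 members without them, while a single pool holding other cells stays open: without 1 pool that value reached 0.148, with 12 arrays in place of 18, but the preset value stayed at or under 0.000113, and the median of the 13 members was 0.62, 0.67 and 0.67 without pools 1, 2 and 3 against 0.51, so that no smaller change was seen without any pool. A lower share of neural cells stays open. Surface ectoderm fell (median -0.50, 0 of 14 members past the test over all genes). Mesenchyme and muscle rose (0.65). Both had adjusted p = 0.0249 with an estimated correlation. These do not decide, since other types need not rise alike and pluripotency fell too (-0.36). Liver or yolk sac type cells stay open as a hypothesis: 14 added genes had a median of 0.10 and p = 0.0933 with an estimated correlation (0.0420 preset, unadjusted), 1 of them rose, and the abundant SELENOP was at 590.1 against 434, APOC1 at 117 against 123 and ALB at 23.8 against 18.6. Choroid plexus cells may also contribute: 10 genes, of which OTX2 is also in the forebrain list, without TTR (endoderm list) and MSX1 (dorsal and BMP lists), had a median of -0.00, and camera gave an unadjusted value of 0.449 with an estimated correlation and 0.314 at the preset one. These values met the bound set beforehand against this explanation, and the reading was changed to undecided after they were seen, because a median near 0 over members that went both ways does not decide: HTR2C rose, FOLR1 (1706 against 2759), ENPP2 (1169.7 against 926) and OTX2 (2759 against 3557) had high baselines, and KL, PRLR and SLC4A5 lay near the floor.

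The 7 retina and lens genes seen first (SIX6, CRYAB, FOXE3, ALDH1A1, ALDH1A3, CRB1 and NR2E1) had a median log2 change with bFGF at day 17 of -1.96. A single pool holding other cells and the 4 arrays with raised low signals both stay open, since these genes were chosen for their fall and the listed genes whose values had not been seen were not called with all arrays either, so that their unadjusted values of up to 0.360 without 1 pool and of 0.156 without the 4 arrays, with an estimated correlation, do not decide; their medians were -0.31, -0.39 and -0.46 without pools 1, 2 and 3 and -0.39 without the 4 arrays, against -0.33. A smaller retina and lens programme with bFGF stays open as a hypothesis: the 6 listed genes whose values had not been seen (RAX, VSX1, CRX, CRYAA, PROX1 and RCVRN) had a median of -0.33 and p = 0.138 with an estimated correlation (0.0849 preset, unadjusted). The most abundant of these without bFGF was PROX1, at 46.3 ± 27.6 with bFGF against 90.5 ± 70.4, then CRYAA, at 15.5 ± 13.6 against 73.9 ± 17.4. ALDH1A1 and ALDH1A3 are also in the retinoic acid list, and SIX6 and RAX in the forebrain list.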
